A study of Mus musculus with 4 samples.

How the data were processed

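Total RNA from tissue holding thalamus and hypothalamus of mice at postnatal day 14 was measured on one-colour (Cy3) Agilent 4x44K whole-genome arrays, 1 array per sample, with 2 dark-reared and 2 control samples grouped by the labels. The spot intensities were made with Agilent Feature Extraction 10.7.3.1, per the file headers (10.7 per the submitters' processing notes); the processed signal is a background-subtracted and detrended intensity of 1 array, with no scaling between arrays. The authors also deposited log2 values per probe, whose medians were 6.84 on every array and which correlated at 0.999 to 1.000 across probes with log2 of the processed signal of the same array; their distributions looked quantile normalized, and the method is not given in the sources used here. These log2 values were used only as an alternative.

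Each array had 45018 spots, 43379 of them not controls, for 41174 probes, of which 245 were spotted more than once. Spots called outliers by the scanner software (100 in dark-reared 1, 96 in dark-reared 2, 103 in control 1 and 79 in control 2) were left out and the spots of a probe averaged. Each array's 75th percentile of processed signal over the probes (802, 784, 792 and 772 in the same order) was subtracted on the log2 scale. Names came from the RefSeq accessions of the probes, matched to a table of RefSeq symbols of mouse assembly GRCm38.p6 used for names alone; 26918 probes got 1 of 18350 symbols and 14256 had none. The array annotation refers to mm9, and no position is given. Probes well above background on both arrays of at least 1 group were kept (28442), and 1 probe stood for each gene, the brightest one. This left 21424 genes, 14326 with a symbol and 7098 probes without, of which 19695 (91.9%) were well above background on all 4 arrays. The signal over background and the 4 arrays limit the precision.

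Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over all genes tested, threshold 0.05). Besides the test, genes with a log2 difference of at least 1 and both values of one group above both of the other were counted. Where no array of a group was well above background, the group's values were raised to the lowest signal that counted as well above background on that array. The fold is then given as at least the resulting one. That bound holds for the main scaling alone and does not allow for noise. The 33 gene lists were fixed before the data were examined, as were the main test and the other settings, except where said below. The 30 lists with at least 5 tested members were compared with the other genes by camera in limma with its preset correlation of 0.01. Benjamini-Hochberg adjustment was over the lists. An estimated correlation and fry were alternatives. With an estimated correlation camera tests on the residual degrees of freedom, few with 4 arrays, where the preset uses the number of genes. Habenula and pineal lists had fewer members, and the sex-chromosome list was kept as a check of the samples.

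Genes are named by a rule fixed before the data were examined. In each direction it takes 12 genes with an official symbol, first those past the adjusted threshold by size, then those with at least a 2-fold difference and no overlap by unadjusted p. It also takes up to 6 members of each list with the largest absolute difference, and Oxt, Avp, Fos, Arc, Npas4, Bdnf, Per1, Per2, Crh, Trh, Tcf7l2, Mbp, Gfap, Ttr, Xist and Ddx3y in every case. Crh had no named probe and Xist was not tested. Of the genes that the rule picked, 1 is not reported here.

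Control 1 was on slide 1, dark-reared 1 on slide 2, and dark-reared 2 and control 2 on slide 3, per the file headers, and all were scanned on 1 day. Slide as a fixed term leaves no residual degrees of freedom, so the blocked value is the difference within slide 3, which has no test. Alternatives were the median or quantile normalization in place of the 75th percentile, normexp background correction with an offset of 50, the deposited log2 values, no filter, a filter on all 4 arrays, outlier spots kept, every probe tested, the mean of a gene's probes, eBayes with trend and robust, the replicate number as a block, and each array left out in turn, which leaves 1 sample assumed to vary like the other group. The planned normexp was to use mean spot signals, which the files do not hold, so median signals were used. Its background fit failed on control 2, where 4 spots had a local background over 10 times the median and a lowest background-subtracted signal of -15715.5: the fitted background mean was -236 there, against -1.90, -5.70 and 2.97 in dark-reared 1, dark-reared 2 and control 1. After seeing this, a setting was added in which local backgrounds called outliers were replaced by the median of the array (fitted means -5.28, -5.62, 0.03 and -4.25 in dark-reared 1, dark-reared 2, control 1 and control 2).

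The gene test was tested on simulated data for the comparison of 2 samples with 2, over 21420 genes with variances drawn from the distribution that limma fitted to these arrays. True log2 changes of 1, 2 and 4 were recovered past the adjusted threshold in 0%, 11.9% and 75.8% of genes, and with 0.1 times the variance in 68.7%, 95.5% and 98.5%. At the full variance 6 unchanged genes were called, 5.07% had an unadjusted p under 0.05, and 557 reached a 2-fold difference without overlap. These genes were drawn independently of each other. Groups did not overlap in 33.8% of them, against 19.0% of the real genes, of which 255 were 2-fold apart without overlap. The rates of recovery and of false calls thus need not hold for the real arrays. In simulated lists, whose genes were drawn independently, a shifted list was found with the preset correlation. No other was called in that run, and 20 runs without any shift gave 1 call. Genes of real lists moved together, with an estimated correlation of 0.965 for myelin genes, so these runs do not give the rate of false calls here. The shifted list was not run with an estimated correlation or fry. A list moved on 1 array alone was called with the preset correlation (adjusted p = 0.00277) and not with an estimated correlation (adjusted p = 0.971) or fry (adjusted p = 0.736). These alternatives passed no list of the real data either, so this does not show that they tell a shift on 1 array from a group shift.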

Results

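Gene expression was measured at postnatal day 14 in mouse brain tissue holding the thalamus and the hypothalamus. The question was whether rearing without visual input changes expression in this tissue. Dark-reared mice came from dams moved to an opaque covered cage 1 to 4 days before birth, were tended under dim red light and stayed there until sampling. Control mice were kept on a daily light cycle. Each group had 2 samples that the labels call biological replicates, without giving the number of animals behind a sample. Each sample was hybridised to its own one-colour Agilent array. Of 41174 probes, 70.6% gave a signal well above background in dark-reared 1, 70.9% in dark-reared 2, 73.3% in control 1 and 65.9% in control 2, and no spot was saturated. Values below are log2 signals relative to the 75th percentile of the same array. The number of arrays limits the precision: with 2 samples against 2, an exact two-sided permutation test cannot give a p below 0.333. Dark-reared 2 and control 2 were hybridised on the same slide, and differences within that slide are given for the gene lists and for part of the genes.

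Transcripts of the sex chromosomes differed between samples of the same group. Xist, the RNA that silences the X chromosome in female cells, had log2 values of 3.41 in dark-reared 1 and 3.77 in control 1, against -5.83 in dark-reared 2 and -6.49 in control 2, where it was not well above background. Ddx3y, a Y-linked RNA helicase, had log2 values of -0.33 in dark-reared 1, 1.05 in dark-reared 2, -6.56 in control 1 and 1.16 in control 2. Dark-reared 1 thus gave signal for both genes, control 1 for Xist without Ddx3y, and the samples on the shared slide for Ddx3y without Xist. Across all 3 tested Y-linked genes the lowest value was in control 1. Xist itself did not pass the detection filter, so it has values and no test. The labels do not give the sex of the animals, and sex itself was not a term in any comparison below. Xist signal was present in 1 sample of each group, and the replicate number, used as a block in an alternative, splits the samples in the same way. Ddx3y was not balanced so, its signal being missing in control 1 alone. The remaining difference in sex content between the groups cannot be told apart from rearing with these 4 samples.

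No gene passed the test between dark-reared and control mice. Of 21424 genes tested with limma, 0 had a Benjamini-Hochberg adjusted p under 0.05, and the lowest adjusted p was 0.298, for the olfactory receptor gene Olfr152. An unadjusted p under 0.05 was found for 271 genes, where chance alone gives 1071.2. A difference of at least 2-fold with both arrays of one group above both of the other was found for 255 genes, 91 higher and 164 lower in dark-reared mice. Groups that did not overlap made up 19.0% of all tested genes, against the 33.3% that chance gives for 2 against 2. In 79 of the 255 genes one group was not well above background on any array, and 77 were well above background on all 4 arrays, of which 16 were higher and 61 lower in dark-reared mice. The count was 23, 4 higher and 19 lower, when the background was removed with normexp after outlying local backgrounds had been replaced, a setting chosen after the data were seen. With the planned normexp, whose background fit failed on control 2, it was 152, 1 higher and 151 lower, and the median of all genes moved from -0.01 to -0.12. Without the filter on dim probes there were 808, and leaving out 1 array gave 1208 without dark-reared 1, 1060 without dark-reared 2, 896 without control 1 and 969 without control 2.

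The genes with the lowest p among those at least 2-fold apart without overlap were picked, 12 in each direction, and none of the 23 reported passed the adjusted threshold. The brightest was Pisd-ps3, a transcribed pseudogene related to phosphatidylserine decarboxylase (NR_003518). Its log2 signal was 5.24 ± 0.17 (SD, n = 2) in dark-reared samples and 3.56 ± 0.03 (SD, n = 2) in controls, a difference of 1.69 with a limma standard error of 0.16 and an adjusted p of 0.904. Both of its detected probes were higher in dark-reared mice, and the difference within the shared slide was 1.59. Met, which encodes the hepatocyte growth factor receptor, differed by 1.96 (standard error 0.34), from -3.36 ± 0.32 (SD, n = 2) in controls to -1.40 ± 0.53 (SD, n = 2) in dark-reared samples; 2 of its 3 detected probes had that sign. Tbr1, a transcription factor of cortical glutamatergic neurons, differed by 1.09 (standard error 0.20), and by 1.13 within the shared slide. The plasma protein precursor gene Kng1 was at least 3.84-fold higher in dark-reared samples at the main setting, its controls being not well above background. Its log2 difference was 0.25 under the planned normexp and 1.26 with the replaced backgrounds, both under that bound of 1.94 in log2. Gsta2, Pbp2, Aldh1a7, Nfe2, Ccl7, Gem and Atp6v0a4 were also higher in both dark-reared samples, and each of these took the opposite sign under the planned normexp. With the replaced backgrounds all of these kept their sign, at differences from 0.20 (Pbp2) to 0.65 (Gem).

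Genes named as lower in dark-reared mice were mostly dim, and none passed either. They included the olfactory receptor genes Olfr152, Olfr259, Olfr360, Olfr1394 and Olfr570. At the main setting Olfr152 was at least 3.71-fold lower and Olfr259 at least 2.85-fold lower, both being not well above background in dark-reared samples. Olfr570 was measured in all samples and differed by -1.71 (standard error 0.20), from -0.04 ± 0.14 (SD, n = 2) in controls to -1.75 ± 0.24 (SD, n = 2) in dark-reared samples. Ghsr, the ghrelin receptor, differed by -1.49 (standard error 0.19), and Trp73, a member of the p53 family, by -1.57 (standard error 0.22). Avpr1b, a vasopressin receptor, was at least 3.31-fold lower, with log2 values of -7.40 and -6.29 in dark-reared samples against -3.68 and -3.31 in controls. F11, Prss32, Adra2b and Sla2 completed the set. With the replaced backgrounds all of these lower genes kept their sign, at differences from -0.47 (Sla2) to -1.49 (Olfr570). Olfr152 was then at -0.99, Olfr259 at -0.90 and Avpr1b at -1.04, each a smaller fall than its bound at the main setting. Of the 23 genes, 13 had a group in which no array was well above background. Within the shared slide all of the genes named here had the sign of the group difference, as it must where groups do not overlap.

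**Figure D1:**
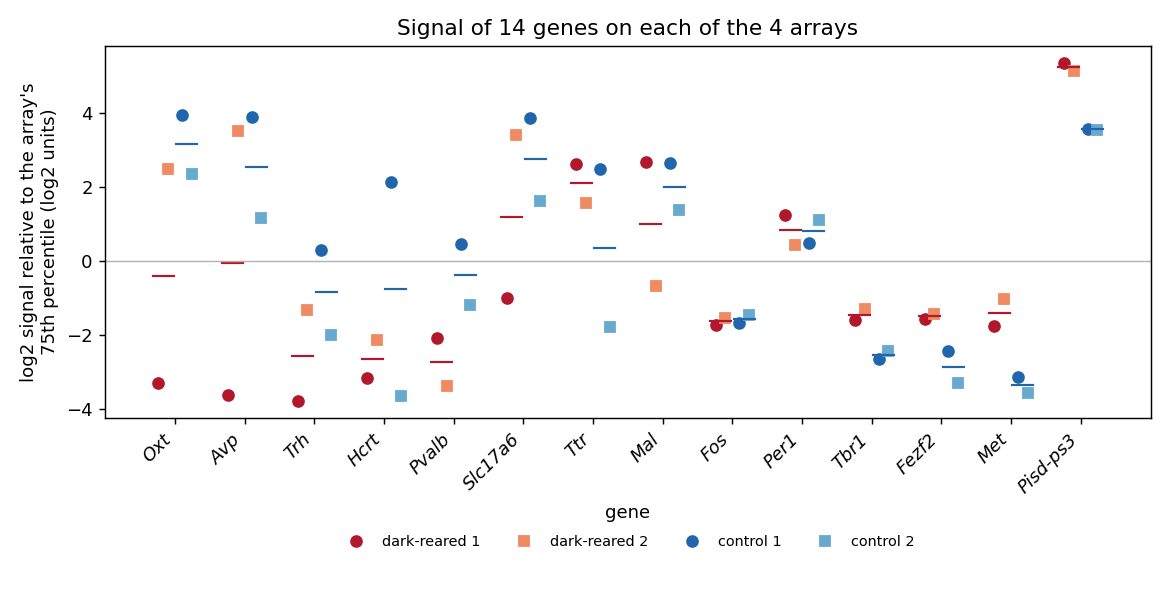
Log2 signal relative to the 75th percentile of the array (vertical axis, log2 units) of 14 genes (horizontal axis) on each of the 4 arrays, with a point per array and a line at each group's mean of 2 samples. Oxt lies at -3.32 in dark-reared 1 and between 2.36 and 3.95 on the other arrays, while Pisd-ps3 lies at 5.36 and 5.13 in dark-reared samples and at 3.58 and 3.54 in controls.

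The oxytocin gene Oxt (NM_011025) was followed as a result of its own. Its mean log2 signal was -0.42 ± 4.10 (SD, n = 2) in dark-reared samples and 3.16 ± 1.12 (SD, n = 2) in controls, a difference of -3.58 with a standard error of 2.14. The difference did not pass in limma, with an unadjusted p of 0.171 and an adjusted p of 1.00, and the groups overlapped. The low mean came from dark-reared 1 at -3.32, since dark-reared 2 at 2.48 lay between control 2 at 2.36 and control 1 at 3.95. Within the shared slide Oxt differed by 0.12, the opposite sign. Without dark-reared 1 the difference was -0.68, and without dark-reared 2 it was -6.48.

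Neuropeptide genes were low in dark-reared 1 in part of the cases. Avp, which encodes vasopressin, had log2 values of -3.62 in dark-reared 1, 3.52 in dark-reared 2, 3.89 in control 1 and 1.17 in control 2, a difference of -2.58 with a standard error of 2.72 and of 2.35, the opposite sign, within the shared slide. Trh, the precursor of thyrotropin-releasing hormone, was lowest in dark-reared 1 at -3.79 and highest in control 1 at 0.30, with a group difference of -1.72 and 0.65 within the shared slide. Hcrt, the orexin precursor, stood highest in control 1, at 2.13, and lowest in control 2, at -3.66. Crh had no named probe. Of 22 tested neuropeptide genes 17 were lower and 5 higher in dark-reared mice, with a median log2 difference of -0.31, and 10 had their lowest value in dark-reared 1. The list passed in camera with its preset correlation (adjusted p = 0.0129) and not with an estimated correlation (adjusted p = 0.793), and its median within the shared slide was 0.25. With dark-reared 1, dark-reared 2, control 1 or control 2 left out the median was -0.29, -0.49, -0.28 or -1.23, and the call ended without dark-reared 1 (adjusted p = 0.962) and without control 1 (adjusted p = 0.698). Over 17 settings the adjusted p ran from 1.85e-05 to 0.962. Among 9 tested genes of the oxytocin and vasopressin system, 4 were higher and 5 lower (camera adjusted p = 0.220), and the list was called toward lower values without dark-reared 2; 1 gene, Avpr1b, passed when adjusted over the list alone (adjusted p = 0.0151) and 0 over all genes tested. Of 14 genes for peptide processing and dense-core vesicles 10 were lower, among them Scg2, Pcsk1 and Chga, and the list did not pass (camera adjusted p = 0.263); its median of -0.10 turned to 0.01 under the planned normexp. The oxytocin list's median of -0.04 turned to 0.0038 with the replaced backgrounds. Its member Avpr1b was not well above background in either dark-reared sample. Within the shared slide the medians were 0.12 for the oxytocin list and 0.04 for peptide processing.

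Camera with its preset correlation placed 12 of 30 gene lists past the threshold, 5 toward higher and 7 toward lower values in dark-reared mice. With an estimated correlation 0 passed, and 0 passed in fry, which asks whether a list's genes move on balance one way. Neither was run on the simulated shifted list, so these 0 counts cannot tell a shift from none. The cortex and hippocampus list had an estimated correlation of -0.048, below the preset one. Its unadjusted camera p still rose from 0.000615 with the preset to 0.0657, so a higher correlation among its genes did not end that call. With an estimated correlation camera has only the residual degrees of freedom of the 4 arrays. A list can thus fail there whatever its correlation, wherever that adjusted p is given here. None of the 12 kept its call in every fit that left out 1 of the 4 arrays, so the medians with dark-reared 1, dark-reared 2, control 1 or control 2 left out are given below in that order. Under the planned normexp the calls for neuropeptides (adjusted p = 0.148), thalamus (adjusted p = 0.386), cortex and hippocampus (adjusted p = 0.0994), ependyma (adjusted p = 0.0616), heat shock (adjusted p = 0.376) and proliferation (adjusted p = 0.466) ended. With the replaced backgrounds 11 of the 12 kept call and direction. Under the planned normexp 5 did, and 1 was called in the opposite direction. The lists called there alone among the scalings were excitatory synapse (adjusted p = 0.0345), inhibitory synapse (adjusted p = 0.00469), microglia (adjusted p = 0.00339) and ribosomal proteins (adjusted p = 2.20e-09), all toward higher values. Adjusted over each list alone, 1 gene in 1 list passed (Avpr1b), and over all genes tested 0 passed. With the preset correlation, replicate 1 arrays against replicate 2 arrays gave 11 lists, and dark-reared 1 with control 2 against dark-reared 2 with control 1 gave 9.

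Markers of the brain regions in the sample were low in dark-reared 1. Of 13 hypothalamus markers 11 were lower in dark-reared mice, with a median of -0.51, and 11 had their lowest value in dark-reared 1, whose mean deviation from the 4-array mean was -0.99 against 0.38 in dark-reared 2, 0.49 in control 1 and 0.12 in control 2. Resp18, a neuroendocrine secretory protein gene, had values of 0.45, 2.80, 3.13 and 2.10 in that order. Irs4, an insulin receptor substrate found in the hypothalamus, was lower in both dark-reared samples, at a difference of -0.80 with a standard error of 0.23, without passing. The hypothalamus list passed with the preset correlation (adjusted p = 0.00313) and not with an estimated correlation (adjusted p = 0.793). Its median was 0.34 within the shared slide and, with each array left out, 0.42, -1.05, -0.18 and -0.98. The call ended without dark-reared 1 (adjusted p = 0.506) and without control 1 (adjusted p = 0.0928), and over 17 settings the adjusted p ran from 1.06e-05 to 0.506. Of 19 thalamus markers 15 were lower, with a median of -0.55, and 11 were lowest in dark-reared 1. Their mean deviation was -0.95 in dark-reared 1, 0.45 in dark-reared 2, 0.84 in control 1 and -0.34 in control 2, so control 1 stood out on the high side. Ramp3, for example, lay at 3.32 in control 1 against 0.93 in dark-reared 1, 1.04 in dark-reared 2 and 1.05 in control 2. Slc17a6, the vesicular glutamate transporter of thalamic neurons, had values of -1.02, 3.41, 3.88 and 1.63 on dark-reared 1, dark-reared 2, control 1 and control 2. Tcf7l2, a transcription factor of the developing thalamus, differed by -0.60 with a standard error of 0.76, and by 0.87 within the shared slide. The thalamus list passed with the preset correlation (adjusted p = 0.0278) and not with an estimated correlation (adjusted p = 0.793); its median was 0.87 within the shared slide and, with each array left out, 0.12, -0.96, 0.12 and -1.32. That call ended without dark-reared 1 (adjusted p = 0.444), without control 1 (adjusted p = 0.529) and without the filter on dim probes (adjusted p = 0.168), and over 17 settings the adjusted p ran from 2.63e-06 to 0.529. All 6 tested pituitary markers were lower (preset adjusted p = 0.0228, estimated correlation adjusted p = 0.793), with Gh not well above background in dark-reared samples and at least 1.45-fold lower; the call ended without dark-reared 1 (adjusted p = 0.481), without control 2 (adjusted p = 0.552) and without the filter (adjusted p = 0.0879), the lowest adjusted p over 16 settings being 0.00141. Of the 6 pituitary markers, Cga differed by -0.0034 and lay above 0 with median or quantile normalization and with the deposited values. Ghrhr, with the largest fall, was well above background in only 1 dark-reared sample. With the filter on all 4 arrays too few pituitary markers were left for the list test. The pituitary median was -0.44, -0.34 within the shared slide and, with each array left out, -0.03, -0.67, -0.73 and -0.15. The 4 tested habenula markers and the 4 tested pineal and photoreceptor genes were too few for the list test at the main setting, each with 2 higher and 2 lower, and medians of 0.95 and 0.17 within the shared slide. Where more members were tested, habenula markers were called toward higher values without dark-reared 1, and pineal and photoreceptor genes toward lower values without the filter on dim probes.

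Markers of forebrain regions next to the sample differed between arrays as well. Of 18 cortex and hippocampus markers 11 were higher and 7 lower in dark-reared mice, with a median of 0.29 that turned to -0.01 under the planned normexp, and 5 were higher in both dark-reared samples than in both controls. With the replaced backgrounds the median was 0.23 (camera adjusted p = 0.00289). Fezf2, a transcription factor of deep-layer cortical neurons, had values of -1.58 and -1.43 in dark-reared samples against -2.45 and -3.30 in controls, and Tbr1 belongs to the same list. The list passed with the preset correlation (adjusted p = 0.00369) and not with an estimated correlation (adjusted p = 0.793); adjusted over the list alone, 0 members passed. Its median was 0.28 within the shared slide and, with each array left out, 0.12, 0.67, 0.16 and 0.34; the call ended without dark-reared 1 (adjusted p = 0.281), and over 17 settings the adjusted p ran from 0.00144 to 0.281. Striatum markers did not pass in camera (10 of 14 higher, median 0.04, adjusted p = 0.916), and within the shared slide 13 were lower and 1 higher, with a median of -1.49. With 1 array left out camera called the list toward lower values without dark-reared 1 and without control 1, and toward higher values without dark-reared 2 and without control 2. Their mean deviations were 0.66 in dark-reared 1 and 0.54 in control 2 against -0.64 in dark-reared 2 and -0.56 in control 1. The dopamine receptor gene Drd1, for example, had values of 2.71, 1.33, 1.15 and 2.52 on dark-reared 1, dark-reared 2, control 1 and control 2.

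**Figure D2:**
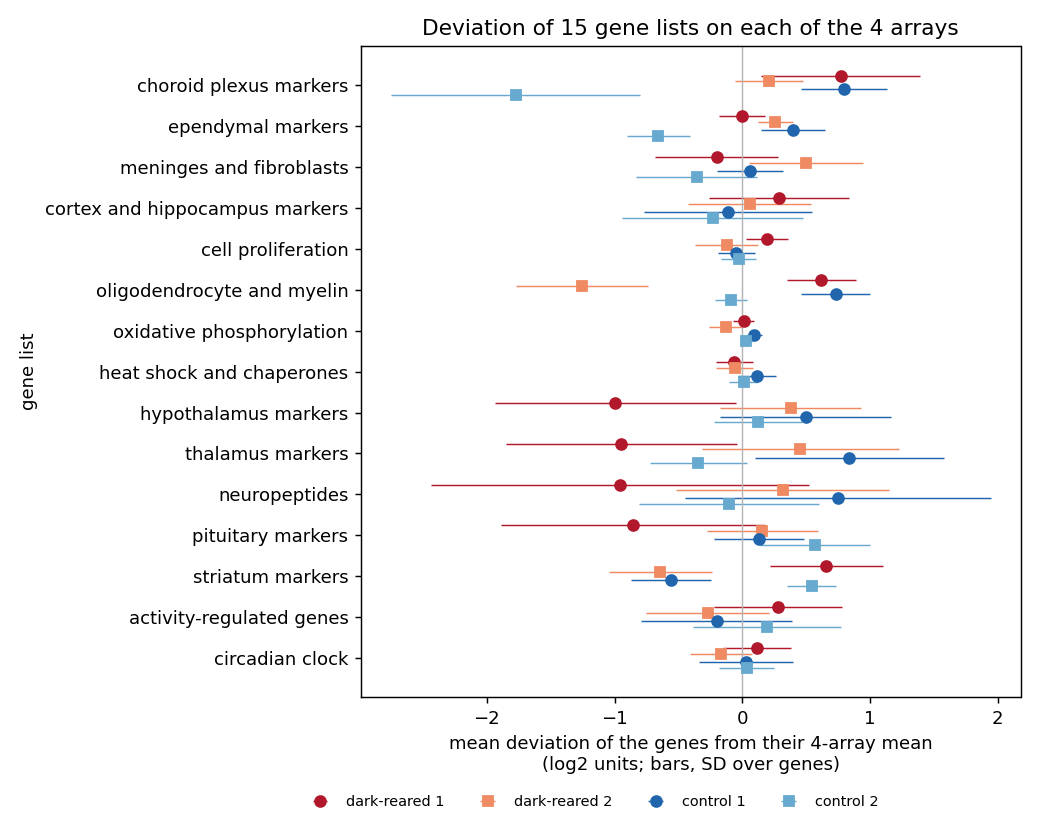
Mean deviation of the genes of 15 lists from their own 4-array mean (horizontal axis, log2 units) for each array, with bars for the SD over the list's genes and lists on the vertical axis. Choroid plexus markers lie at -1.77 in control 2, myelin genes at -1.26 in dark-reared 2, and hypothalamus and thalamus markers at -0.99 and -0.95 in dark-reared 1.

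Choroid plexus markers were higher in dark-reared mice in 17 of 18 cases, with a median of 0.96, and 17 of 18 had their lowest value in control 2. Ttr, the thyroxine carrier that choroid plexus secretes, had log2 values of 2.63 and 1.56 in dark-reared samples, 2.49 in control 1 and -1.78 in control 2, a difference of 1.74 with a standard error of 1.57. The water channel gene Aqp1 had values of 0.97, 0.17, 1.07 and -3.24 in the same order. The list passed with the preset correlation (adjusted p = 0.000254) and not with an estimated correlation (adjusted p = 0.793). Its median was 2.07 within the shared slide, which holds control 2, and, with each array left out, 0.74, 1.15, 2.26 and -0.32. Without control 2 camera called the list in the opposite direction (adjusted p = 0.0492), without dark-reared 1 the call ended (adjusted p = 0.247), and over 17 settings the adjusted p ran from 1.81e-33 to 0.247. Ependymal markers, genes of the ciliated ventricle lining, were higher in 11 of 12 cases and lowest in control 2 in 11 (median 0.24, preset adjusted p = 0.0202, estimated correlation adjusted p = 0.793). Foxj1, the regulator of motile cilia, was higher in both dark-reared samples by 0.63 with a standard error of 0.15, without passing. The ependymal median was 0.96 within the shared slide and, with each array left out, 0.38, 0.04, 0.80 and -0.40. The list was called in the opposite direction without control 2 (adjusted p = 0.0174), the call ended without dark-reared 1 (adjusted p = 0.136) and without dark-reared 2 (adjusted p = 0.325), and the lowest adjusted p over 17 settings was 1.34e-14. Of 15 genes of meninges and fibroblasts 11 were higher (median 0.19, preset adjusted p = 0.0110, estimated correlation adjusted p = 0.793), with a median of 0.87 within the shared slide and, with each array left out, 0.56, 0.0045, 0.25 and 0.05. That call ended without dark-reared 2 (adjusted p = 0.310) and without control 2 (adjusted p = 0.296), the lowest adjusted p over 17 settings being 3.75e-05. Slc13a4, a sulfate transporter of the meninges and choroid plexus, had values of 1.86, 1.93, 1.85 and -0.48 on dark-reared 1, dark-reared 2, control 1 and control 2.

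All 24 tested oligodendrocyte and myelin genes had a lower mean in dark-reared mice, with a median of -0.73, and 23 had their lowest value in dark-reared 2. Mbp, myelin basic protein, had log2 values of 7.48 in dark-reared 1, 5.47 in dark-reared 2, 7.53 in control 1 and 6.88 in control 2. Mal, a myelin proteolipid gene, had values of 2.68, -0.69, 2.64 and 1.39 in the same order, and 0 of the 24 genes separated the groups. The list passed with the preset correlation (adjusted p = 0.000254) and not with an estimated correlation (adjusted p = 0.793). Its median was -1.22 within the shared slide and, with each array left out, -1.74, 0.30, -0.24 and -1.11. Without dark-reared 2 the list was called in the opposite direction (adjusted p = 0.0215), without control 1 the call ended (adjusted p = 0.529), and over 17 settings the adjusted p ran from 8.70e-17 to 0.529. Of 9 oligodendrocyte precursor genes 6 were lower (adjusted p = 0.220), with a median of -0.30 within the shared slide. Astrocyte genes were split 8 higher and 7 lower with a median of 0.03 and a mean of -0.11 (adjusted p = 0.712); Gfap, the astrocyte filament gene, differed by 0.57 with a standard error of 0.43, and by 1.37 within the shared slide. Microglia (13 of 17 higher, adjusted p = 0.183), blood vessels (12 of 20 higher, adjusted p = 0.385) and red blood cells (4 of 6 higher, adjusted p = 0.562) did not pass in camera. Within the shared slide all 17 microglia genes were lower, with a median of -0.36, and so were 17 of 20 blood vessel genes, with a median of -0.22. Camera called microglia toward higher values without dark-reared 2 and without control 2 and toward lower values without control 1, and blood vessels toward higher values without dark-reared 2. Medians on the shared slide were -0.07 for red blood cells and 0.20 for astrocytes.

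Of 34 oxidative phosphorylation genes 30 were lower in dark-reared mice and 17 were lower in both samples than in both controls, with a median of -0.12 that turned to 0.05 under the planned normexp (adjusted p = 0.00339, opposite direction). With the replaced backgrounds the median stayed at -0.12 (camera adjusted p = 0.000425). It shrank to -0.04 with quantile normalization (camera adjusted p = 0.0379), to -0.07 with the deposited values and to -0.09 with median normalization, so its size depended on the scaling. Cox7b and Atp5b, subunits of cytochrome oxidase and ATP synthase, differed by -0.25 and -0.24. The list passed with the preset correlation (adjusted p = 0.000277) and not with an estimated correlation (adjusted p = 0.793); its median was -0.13 within the shared slide and, with each array left out, -0.18, -0.07, -0.09 and -0.17. The call ended without dark-reared 2 (adjusted p = 0.360) and without control 1 (adjusted p = 0.188), the lowest adjusted p over 17 settings being 0.000128. All 16 heat shock and chaperone genes had a lower mean (median -0.13, preset adjusted p = 0.0129, estimated correlation adjusted p = 0.793), and Hsph1 differed by -0.25 with a standard error of 0.22; the median was -0.11 within the shared slide and, with each array left out, -0.10, -0.11, -0.10 and -0.20. That call ended without any one of the arrays, with adjusted p values between 0.0697 and 0.445, without the filter on dim probes (adjusted p = 0.182), and under the planned normexp, where the list stood above the other genes (adjusted p = 0.376). The lowest adjusted p over 17 settings was 0.00690. Of 23 proliferation genes 19 were higher (preset adjusted p = 0.0278, estimated correlation adjusted p = 0.793), with a median of 0.07 that was -0.03 within the shared slide and -0.04 under the planned normexp. With each array left out the median was -0.04, 0.21, 0.08 and 0.07, and the call ended without dark-reared 1 (adjusted p = 0.444), control 1 (adjusted p = 0.192) and control 2 (adjusted p = 0.111). The proliferation call also ended with quantile normalization (adjusted p = 0.0522), the replaced backgrounds (adjusted p = 0.0503), every probe tested (adjusted p = 0.0571) and the mean of a gene's probes (adjusted p = 0.0535), the lowest adjusted p over 17 settings being 0.000586.

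Genes that follow neuronal activity did not pass as a list, and their values differed within groups. Fos, the immediate early transcription factor, had a mean log2 signal of -1.64 ± 0.13 (SD, n = 2) in dark-reared and -1.58 ± 0.16 (SD, n = 2) in control samples, a difference of -0.06 with a standard error of 0.17. Arc differed by -0.08 (standard error 0.58), Npas4 by 0.45 (standard error 0.37) and Bdnf by -0.20 (standard error 0.97), and Arc and Npas4 took the opposite sign under the planned normexp. With the replaced backgrounds Arc and Npas4 kept their sign. Arc differed by -1.18, Npas4 by -0.14 and Bdnf by 1.70 within the shared slide. Nr4a2, an orphan nuclear receptor, was lower in both dark-reared samples, at a difference of -0.95 with a standard error of 0.36, without passing. Of 24 activity-regulated genes 15 were higher and 9 lower (median 0.03, adjusted p = 0.712), and within the shared slide 7 were higher and 17 lower, with a median of -0.44. Without dark-reared 2 camera called the list toward higher values. Of the clock genes, Per1 differed by 0.03 (standard error 0.38) and Per2 by 0.09 (standard error 0.30). Per2 took the opposite sign under the planned normexp and not with the replaced backgrounds. Of 21 clock genes 11 were higher, with a median of 0.00 and a mean of -0.06 (adjusted p = 0.826). Of 15 glucocorticoid-responsive genes 11 were higher (adjusted p = 0.0844), a list that camera called toward higher values under the planned normexp (adjusted p = 0.00469), with the replaced backgrounds (adjusted p = 0.0297) and without the filter on dim probes. It was also called so without dark-reared 2 and without control 1. On the shared slide Per1 differed by -0.68 and Per2 by -0.44, and the medians were -0.13 for clock and 0.06 for glucocorticoid-responsive genes.

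Among genes of perineuronal matrix and of critical-period plasticity, 12 of 19 were lower (adjusted p = 0.173). Pvalb, the calcium buffer of fast-spiking interneurons, had values of -2.10 and -3.39 in dark-reared samples against 0.45 and -1.20 in controls, a difference of -2.37 with a standard error of 0.76 and -2.18 within the shared slide, and did not pass. Kcnc1, a potassium channel gene of fast-spiking neurons, differed by -0.47 with a standard error of 0.21. Excitatory synapse genes were split 14 higher and 14 lower (median 0.01, mean -0.06, adjusted p = 0.916), inhibitory synapse genes 10 higher and 11 lower (adjusted p = 0.916), and genes of monoamine and acetylcholine systems 10 higher and 13 lower (adjusted p = 0.663). Th, the first enzyme of catecholamine synthesis, was lower in both dark-reared samples, at a difference of -0.67 with a standard error of 0.29, without passing. Interferon-stimulated genes (11 of 18 higher, adjusted p = 0.323), ribosomal protein genes (30 of 39 lower, adjusted p = 0.397) and cholesterol synthesis genes (16 of 22 lower, adjusted p = 0.331) did not pass in camera. For ribosomal protein genes the sign of the median turned under quantile normalization and with the authors' deposited values, and under the planned normexp it turned for ribosomal, activity-regulated, clock, peptide processing, inhibitory synapse, habenula and interferon-stimulated genes. With the replaced backgrounds the sign of the median turned for interferon-stimulated genes (-0.0061) and not for the others of these lists. For monoamine genes it turned under quantile normalization and with the authors' deposited values. Within the shared slide the medians were 0.0086 for perineuronal and critical-period, -0.30 for excitatory synapse, 0.09 for inhibitory synapse and 0.23 for monoamine genes. With 1 array left out camera called inhibitory synapse genes toward lower values without dark-reared 2, perineuronal and critical-period genes toward lower and interferon-stimulated genes toward higher values without control 2, and cholesterol synthesis genes toward lower values without dark-reared 1 and without control 2. The medians on the shared slide were 0.0030 for interferon-stimulated, -0.10 for ribosomal protein and -0.05 for cholesterol synthesis genes. Camera's direction and the median had opposite signs for the clock, excitatory synapse, striatum and astrocyte lists.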

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

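In limma the count of genes past the adjusted threshold was 0 in every setting run, with 156 to 1329 genes at an unadjusted p under 0.05. The normexp fit with replaced backgrounds and the crossed pairing were chosen after the data were seen. The 255 genes at least 2-fold apart without overlap became 152 with the planned normexp (1 higher, 151 lower, where 91 were higher and 164 lower before), 23 with replaced backgrounds (4 higher, 19 lower), 808 without the filter on dim probes and 77 with a filter on all 4 arrays; filters change the genes tested, normexp compresses dim signals by its offset, and leaving out 1 array gave 896 to 1208, since fewer values overlap less. It was 245 to 280 in the other settings that change this count. The normexp offset was not varied alone, since the spot signals and the background fit changed with it, so its part in these counts was not tested. With 1 array left out the lower genes were the larger part each time, least so without dark-reared 1 and most without control 2. The 12 lists became 0 with an estimated correlation and 0 with fry, neither of which was run on the simulated shifted list. They became 11 or 12 in the other settings with all arrays, and 6 to 15 with 1 array left out (6 without dark-reared 1, 15 without dark-reared 2). These counts do not hold the same lists: 5 of the 12 kept call and direction under the planned normexp (5 lists called there and not before), 9 without the filter (2 new) and 11 with replaced backgrounds (1 new). With dark-reared 1, dark-reared 2, control 1 or control 2 left out 3, 7, 5 or 6 kept both, with 3, 7, 3 or 5 new. Oxt turned from -3.58 to 0.12 within the shared slide, lay between -6.48 and -0.68 with 1 array left out, and between -3.60 and -2.87 elsewhere. With the planned normexp, where the failed fit on control 2 raised its dim values, 41 of 212 named genes took the opposite sign, where the other scalings gave 1 to 4; 7 of the 41 were genes picked for size: Gsta2 (-0.30), Pbp2 (-0.57), Aldh1a7 (-0.10), Nfe2 (-0.31), Ccl7 (-0.55), Gem (-0.14) and Atp6v0a4 (-0.53); oxidative phosphorylation turned to 0.047 and heat shock, at -0.036, stood above the median of all genes at -0.12. With 1 array left out the list medians that turned ranged from -1.32 to 0.12 for thalamus, -1.05 to 0.42 for hypothalamus, -0.32 to 2.26 for choroid plexus, -0.40 to 0.80 for ependyma, -1.74 to 0.30 for myelin, 0.0045 to 0.56 for meninges (camera's direction turned) and -0.043 to 0.21 for proliferation; thalamus turned without dark-reared 1 and also without control 1, each other list without 1 array, and the cause was not tested. Among 3769 values of 211 named genes besides Oxt, 113 moved by more than the spread between replicates; for genes picked for size, sign and call were compared where a test was run. Same-numbered samples did not deviate together across genes (correlation of deviations -0.158), although Xist followed the number and the replicate 2 arrays share a slide, and the labels state no pairing; with the replicate block 0 genes (274 unadjusted) and 12 lists passed, and it changed no other call. The crossed replicate block gave 0 genes (434 unadjusted) and 12 lists. Slide as a random block was not estimable with 4 arrays, a block for scan day could not be fitted with 1 scan day, and values within the slide give no test for the counts. Signal near background limits the dim genes: 77 of the 255 were well above it on all arrays.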

Other observations

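The tests of tissue content, of the falls in single samples, of the splits and of other probes of dim genes alone were chosen after the results were seen; the test on other probes of all 2-fold genes was not.

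The dark-reared samples differed more from each other than from either control. Their correlation across genes was 0.968, with 2090 genes over 2-fold apart, the most of any pair, where the controls had 1033 such genes and dark-reared 2 with control 1 the fewest, 993. Genes are not independent replicates. The first principal component held 49.8% of the variance, with dark-reared 1 at 46.0 and dark-reared 2 at -48.3 at its ends and control 1 at -10.9 and control 2 at 13.2 between them. Striatum markers followed this order: their mean deviations were 0.66 in dark-reared 1, -0.64 in dark-reared 2, -0.56 in control 1 and 0.54 in control 2. Microglia genes were lowest in control 1 in 13 of 17 cases.

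Oxt and Avp were low in dark-reared 1 alone. Whether Oxt fell by the mean size in each dark-reared sample cannot be decided with 2 samples per group: it lay at -0.68 from the control mean in dark-reared 2, and the 95% prediction half-width from the control SD of 1.12 was 17.5. A tissue piece with less hypothalamus and thalamus is a candidate explanation that also stays open. In dark-reared 1 hypothalamus markers (n = 13) averaged -1.32 and thalamus markers (n = 19) -1.26 against the other 3 samples, beyond the 95% prediction half-width of those samples for the hypothalamus (0.95) and within it for the thalamus (2.99). Dark-reared 1 was picked as the lowest sample, which the half-widths do not allow for. An effect of rearing in 1 sample alone was not tested.

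Choroid plexus markers were higher and myelin genes lower in the dark-reared mean. A shift in both dark-reared samples against both controls cannot be decided with 2 samples per group. Dark-reared 2 minus control 1 gave -0.59 over 18 choroid plexus markers and dark-reared 1 minus control 2 gave 0.71 over 24 myelin genes, the signs opposite to the shifts, within 95% prediction half-widths of 7.11 and 10.4 from the group without the outlying sample. An uneven amount of these tissues in 1 sample also stays open: against the other 3 samples choroid plexus markers lay at -2.37 in control 2, beyond the 95% prediction half-width of 1.64, and myelin genes at -1.68 in dark-reared 2, within that of 2.21, both samples being picked as the lowest. Whether dissection or another cause made these samples differ was not tested.

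The genes with at least a 2-fold difference were mostly dim. Noise of single spots near background stays open: another detected probe had the same sign in 75% (12 of 16 genes, exact 95% interval 47.6 to 92.7), but 10 of these genes were well above background on all 4 arrays. Among the 6 that were not, 83.3% had the same sign (5 of 6, exact 95% interval 35.9 to 99.6), and both intervals hold 50%. The 4 samples make 3 splits, too few for a share under 0.05, of which the real one gave 255 such genes, the lowest of the 3, replicate 1 against replicate 2 gave 463, and the highest other gave 760. The highest one, dark-reared 1 with control 2 against dark-reared 2 with control 1, gave 2893 genes with an unadjusted limma p under 0.05. Replicate 1 against replicate 2 gave 972 and the real split 271. The highest split was picked after the counts were seen, and genes are not independent, so no cause can be read from these counts.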
